A study of Homo sapiens with 6 samples.

How the data were processed

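Messenger RNA libraries were prepared from MOLM-14, NOMO-1 and SKM-1 cells at 72 h after transfection with a scrambled or an NCAM1 shRNA, using an Illumina TruSeq RNA v2 kit and paired 100 bp reads on an Illumina HiSeq instrument, per the labels and the series text. The control_shRNA and NCAM1_knockdown groups hold 3 libraries each, 1 per line. Whether the same hairpin sequence was used in the 3 lines is not given in the sources used here.

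The deposited signal values are gene read counts that the authors divided by 1 size factor per library. The deposited log2 values are a transformation that the authors made of those counts, and its name is not given in the sources used here. bcl2fastq 1.8.4, STAR, HTSeq 0.6.1p1, DESeq2 1.12.4 and genome build hg19 are named in the submitters' processing notes, without their settings. The strand setting of the counting and the gene annotation are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. Genes with near-identical copies (TPSB2, HSPA1A, HSPA1B, the metallothioneins, HLA genes, FCGR3A and FCGR3B) are uncertain, because counting can split or drop their shared reads. The reference annotation used here is of GRCh38, another build, so no coordinates are given and it served only for gene types, GC content and transcript length.

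Every column was a set of whole multiples of 1 step, and dividing by that step gave whole reads for 100% of values at a tolerance of 0.001. This recovered the depth of each library, 41916991 to 47688779 reads. The precision this gives a single library ratio is stated as an exact conditional 95% interval, and a gene at 0 reads is set to a floor of 3 reads in that library. These intervals and floors cover counting error only. The table held 34114 genes. Genes with a mean normalized count of 10 or more over the 6 libraries were tested, 19575 in all.

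The groups, tests, gene lists, naming rule and alternatives were fixed before the data were examined. The main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend, two-sided) on log2(normalized count + 1) with the cell line as a block, Benjamini-Hochberg adjusted, with calls at an adjusted p under 0.05. Fold changes on this scale understate the change of low genes. The pairing comes from the cell line. Deviations from the group means correlated across genes at 0.850, 0.863 and 0.710 between the 2 libraries of MOLM-14, NOMO-1 and SKM-1, and at -0.319 or below between libraries of different lines. The negative values follow largely from subtracting the group means, since deviations within a group cancel out, and add nothing to the pairing. The fit has 2 residual degrees of freedom and 2.81 prior ones. Gene lists with 5 or more tested members (31 of 34) were tested with limma's camera on the same fit, with a preset inter-gene correlation of 0.01 and again with an estimated one, and described with fry. Of 566 list entries 552 were found in the table. Whether camera pools its variances with a trend was settled as part of the same fit, but only after both outcomes had been seen: 8 lists were called with the trend and 4 without it. Cell line contrasts came from the same fit and needed at least a 2-fold difference. Single lines have 1 library per condition. Their lists are described by the percentile of the median among 10000 random lists of the same size matched on mean expression.

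The naming rule took NCAM1, the 12 higher and 12 lower genes of the knockdown comparison with the same direction in 3 lines and a mean of 50 or more, filled by smallest p where too few were called, up to 4 members per described list by p, 4 genes per direction and line with at least 100 normalized counts in 1 library, and per cell line contrast the 6 most positive and 3 most negative. Pseudogenes were passed over by that rule. Genes with clone-type names, X-inactivation transcripts and Y-linked genes were passed over too, which was decided after their values had been seen.

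Alternatives were pseudocounts of 0.5 and 8, no filter and a filter of 50, total-count scaling, quantile normalization, the authors' transformed values, no block, eBayes without trend and with the robust option, edgeR 4.0.16 (TMM, quasi-likelihood) and DESeq2 1.42.0 on recovered reads, an estimated correlation, any fold for the cell line contrasts, and leaving out each line in turn. GC content and transcript length were corrected with loess (span 0.3) on the ratios of each line. Both were known for 97.0% of tested genes and for 100% of the monocyte, sterol and glycolysis lists.

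The steps were tested on simulated data with the real means and depths of 19575 genes and 200 changed genes in the blocked knockdown comparison. With each gene at its own dispersion estimated from these data (median 0.111), limma recovered 0 of 67 genes changed 2-fold, 25 of 67 changed 4-fold and 56 of 66 changed 8-fold, with 4 false calls. For the same genes edgeR recovered 2, 32 and 58, with 9 false calls. In a separate draw with a dispersion of 0.01 for every gene, limma recovered 47, 65 and 64, with 0 false calls. There edgeR recovered 66, 67 and 66, with 13 false calls. Each changed gene had the same fold in all 3 lines and the same dispersion in all libraries. In the data the SD of log2 ratios was 0.55 in MOLM-14, 0.70 in NOMO-1 and 1.43 in SKM-1. The recovered numbers therefore do not carry over to changes that differ between lines. DESeq2 was not simulated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.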

Results

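RNA was sequenced from 3 human acute myeloid leukemia (AML) cell lines, MOLM-14, NOMO-1 and SKM-1, which are established lines grown from patients with that blood cancer. Each line had received either a scrambled control short hairpin RNA (shRNA) or an shRNA against NCAM1 (neural cell adhesion molecule 1, also known as CD56), and was sampled at 72 h. There was 1 library per line and condition, so 3 control libraries and 3 knockdown libraries. Gene-assigned reads numbered 41916991, 45542099 and 43666135 in the control libraries of MOLM-14, NOMO-1 and SKM-1, and 43745763, 45360397 and 47688779 in their knockdown libraries. The 13 mitochondrially encoded protein genes took 5.40% to 8.30% of reads, with mitochondrial ribosomal RNA not counted. Values below are normalized read counts, or log2 ratios of knockdown over control on the log2(normalized count + 1) scale.

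The first question was how far the target of the shRNA differed between the 2 libraries of each line. NCAM1 (ENSG00000149294), a cell surface adhesion protein of the immunoglobulin superfamily, was lower in the knockdown library of all 3 lines. Its normalized read count went from 6004 to 1896 in MOLM-14, a 3.17-fold difference (95% interval 3.003 to 3.342). It went from 1163 to 312 in NOMO-1, a 3.73-fold difference (3.30 to 4.21), and from 12537 to 101 in SKM-1, a 124-fold difference (103 to 151). The mean log2 change was -3.50 ± 2.98 (SD, n = 3 lines). In limma this gave an SE of 1.124 and an adjusted p of 0.779, and the exact two-sided sign-flip p over the 3 lines was 0.25, which is the smallest such a design allows. The intervals cover counting error only, and there is no replicate within a line. In SKM-1, 28.8% of genes with a normalized count of at least 100 in 1 of its libraries differed at least 2-fold. How much of the NCAM1 difference in SKM-1 came from the shRNA cannot be told apart from other differences between its libraries.

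**Figure D1:**
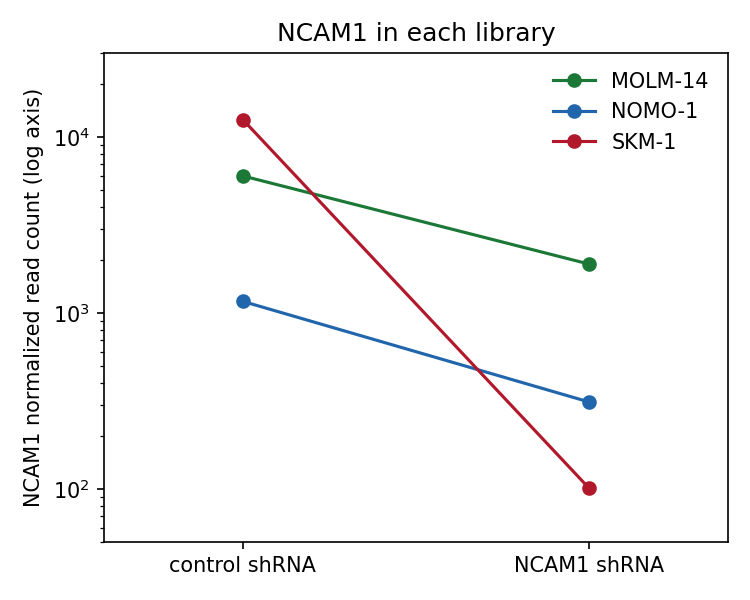
Normalized read count of NCAM1 (log axis) in the control shRNA and NCAM1 shRNA library of each cell line, 1 point per library, with lines joining the 2 libraries of a cell line. The knockdown libraries sit at 1896 (MOLM-14), 312 (NOMO-1) and 101 (SKM-1), each below its own control.

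The main comparison asked which genes moved with NCAM1 knockdown across the 3 lines. Enzymes of cholesterol synthesis were lower in each line: LSS (lanosterol synthase) had a mean log2 change of -1.04 ± 0.12 (SD, n = 3 lines), SQLE (squalene epoxidase) -0.91 ± 0.0020 and FDPS (farnesyl diphosphate synthase) -1.05 ± 0.33. VEGFA, a growth factor for blood vessels that hypoxia induces, was at -0.87 ± 0.036, and SLC6A8, the creatine transporter, at -2.30 ± 0.88. The metalloproteinase ADAM28 was higher, at 2.51 ± 1.04, as was the related ADAMDEC1, at 3.75 ± 2.05. No gene passed limma at an adjusted p under 0.05 among the 19575 tested. At an unadjusted p under 0.05 there were 877 genes, 312 higher and 565 lower. The edgeR quasi-likelihood test on recovered reads also called 0 genes, with 863 at an unadjusted p under 0.05. DESeq2 on the same reads called 43, 11 higher and 32 lower, of which 39 had the same direction in all 3 lines. Without the NOMO-1 pair the 877 genes became 223, 110 higher and 113 lower, so the excess of lower genes was not seen. They became 1389 without the SKM-1 pair, 451 higher and 938 lower, and 1405 with no filter on low values. P values here rest on the spread between cell lines, since each line stands as 1 replicate. In limma this spread is moderated by that of other genes, so the SD beside a gene is not the spread behind its p. SQLE, with an SD of 0.0020, had a limma SE of 0.143.

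With no gene called, the 24 genes named here are the 12 higher and 12 lower ones with the smallest p that moved the same way in all 3 lines, each with an adjusted p of 0.779 in limma. Besides ADAM28 and ADAMDEC1, the higher ones were RSAD2 (viperin, an interferon-induced antiviral enzyme) at 1.17 ± 0.19 (SD, n = 3 lines), the zinc finger gene ZFP3 at 3.21 ± 1.63, PGBD5, derived from a DNA transposase, at 1.71 ± 0.075, and BTLA, an inhibitory lymphocyte receptor, at 1.5002 ± 0.13. PDYN (prodynorphin), SHISA2, ARRDC3, SAMSN1, REEP3 and DYNLT3 had mean log2 changes of 1.97, 1.83, 0.93, 1.15, 1.17 and 1.67. PDYN and BTLA each rest on 0 reads in 1 control library, of SKM-1 and MOLM-14 in turn. Among the lower ones, EGR3, an immediate early transcription factor, was at -2.39 ± 0.35, DUSP8, a phosphatase of MAP kinases, at -2.13 ± 0.65, and XYLT1, which starts proteoglycan chains, at -1.19 ± 0.18. EHD2, TSHZ3 and KIAA1715 (now LNPK) were at -1.78, -1.23 and -1.04. TPSB2, a mast cell tryptase, was at -2.41, and is uncertain because it shares reads with the near-identical TPSAB1. EGR3 and TPSB2 had 0 reads in the SKM-1 knockdown library, where the control had a normalized count of 5.08 for each. DESeq2 called 16 of the 24.

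Of the 31 gene lists tested, 8 were called by camera with its preset inter-gene correlation of 0.01, and 0 with an estimated correlation. When it estimates the correlation, camera also falls back on the residual degrees of freedom, 2 here and fewer with a line left out. Almost no list can pass then, whatever its correlation. For the list of NCAM1 partners the estimate, -0.039, was below the preset, yet the camera p went from 0.0092 to 0.109. For the other called lists the estimate was above the preset, from 0.114 (ATF4 targets) to 0.737 (mitosis). It was 0.543 for MAP kinase output, 0.514 for replication, 0.318 for cholesterol synthesis and 0.294 for glycolysis. The calls of these lists therefore rest on a preset below their own estimate. In them a higher correlation and fewer degrees of freedom act together, and this test does not part the 2. Losing the calls thus shows neither that correlation between genes made them nor that they hold. Among the 8 called lists the unadjusted fry p was under 0.05 only for cholesterol synthesis (0.0267) and NCAM1 partners (0.0186). The fry p was 0.059997 for glycolysis, 0.104 for ATF4 targets and 0.113 for heat shock. For replication, mitosis and MAP kinase output it was 0.4298, 0.463 and 0.54015. By camera with the preset correlation, cholesterol synthesis led. All 19 measured members had a lower mean, and 15 of them were lower in each of the 3 lines, with a median log2 change of -0.77 (adjusted p = 1.25e-15 with the preset correlation, adjusted p = 0.933 with an estimated correlation). Its members with the smallest p were LSS, SQLE, FDPS and INSIG1 (-1.42 ± 0.67, SD, n = 3 lines), which retains the sterol-sensing machinery in the endoplasmic reticulum. For this list 13 genes were lower when adjusted over the list alone, against 0 over all genes tested. DESeq2 called 4 members. In SKM-1, 4 of the 19 were higher and 3 were at least 2-fold lower, with a median of -0.50, at percentile 1.31 of random lists. A fall of that size was not particular to sterol genes in SKM-1, where ribosomal protein genes were at -0.50 and MYC targets at -0.49.

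Genes of glycolysis and hypoxia were lower as well. A lower mean was found for 22 of 23 members, and 17 were lower in all 3 lines, with a median of -0.78 (adjusted p = 5.60e-13, and adjusted p = 0.933 with an estimated correlation). VEGFA came first, followed by ENO2, a neuron-type enolase of glycolysis, at -2.35 ± 1.14 (SD, n = 3 lines), PGK1, which makes ATP in glycolysis, at -0.83 ± 0.23, and ALDOC, an aldolase, at -2.44 ± 1.39. Adjusted over the list alone, 10 genes were lower. The exception was ADM (adrenomedullin), a vasodilator peptide, at 0.23 in MOLM-14, -2.36 in NOMO-1 and 2.75 in SKM-1. DESeq2 called 4 members of this list too.

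Heat shock chaperones were the 1 called list that was higher. All 10 members had a higher mean, 6 of them in every line, with a median of 0.51 (adjusted p = 2.90e-04, and adjusted p = 0.933 with an estimated correlation). HSPH1, a nucleotide exchange factor of HSP70, was at 0.80 ± 0.35 (SD, n = 3 lines), the constitutive HSP70 protein HSPA8 at 0.54 ± 0.39 and HSP90AA1 at 0.49 ± 0.46. HSPA1B, at 0.85, shares reads with HSPA1A and is uncertain. No gene of this list was called when adjusted over the list alone. Without the NOMO-1 pair the median was 0.27, still called with an adjusted p of 0.0257, and adjusted p = 0.873 with an estimated correlation.

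Targets of ATF4 and amino acid synthesis genes were lower, 13 of 18 by their mean and 8 in all 3 lines, with a median of -0.40 (adjusted p = 0.00670, and adjusted p = 0.933 with an estimated correlation). They included TRIB3, a stress-induced pseudokinase, at -0.79 ± 0.29 (SD, n = 3 lines), MTHFD2, a mitochondrial folate enzyme, at -1.12 ± 0.63, and ATF3 and VLDLR at -0.62 and -1.25. NOMO-1 showed no decrease on its own, with 10 of 18 members higher and a median of 0.050. The call was lost without the MOLM-14 pair, though the median stayed at -0.37 (adjusted p = 0.266). Without the SKM-1 pair the median was -0.21 (adjusted p = 0.00130, and adjusted p = 0.754 with an estimated correlation). A list of NCAM1 partners and enzymes that modify it had 11 of 14 members lower, with a median of -0.50 (adjusted p = 0.0357, and adjusted p = 0.933 with an estimated correlation). SPTBN1, a spectrin of the membrane skeleton, was at -0.86 ± 0.52, ST8SIA4, which adds polysialic acid to NCAM1, at -0.54 ± 0.34, and L1CAM and SPTAN1 at -1.002 and -0.41. This call was lost without the MOLM-14 pair, where the median was larger in size (-0.62, adjusted p = 0.0961), and without the SKM-1 pair (median -0.21, adjusted p = 0.202). In both of these lists 0 genes were called when adjusted over the list alone.

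Outputs of MAP kinase signalling had 10 of 14 members lower, 5 of them in all 3 lines, with a median of -0.25 (adjusted p = 0.0324, and adjusted p = 0.933 with an estimated correlation). ETV5 and ETV4, transcription factors that ERK signalling induces, were at -0.62 ± 0.12 and -0.79 ± 0.57 (SD, n = 3 lines), and the ERK phosphatase DUSP6 at -0.46 ± 0.097. SPRED1, an inhibitor of the pathway, was at -0.44 ± 0.033. The lines parted here: without the SKM-1 pair all 14 members were lower in both remaining lines, with a median of -0.60 (adjusted p = 4.70e-10, and adjusted p = 0.754 with an estimated correlation). Without the MOLM-14 pair the median was -0.10 (adjusted p = 0.542) and without the NOMO-1 pair -0.0078 (adjusted p = 0.438). The related immediate early genes were not called (median -0.29, adjusted p = 0.0579, and adjusted p = 0.933 with an estimated correlation), though EGR3 and NR4A1, an orphan nuclear receptor at -1.19 ± 0.29, were lower when adjusted over the list alone. Without the SKM-1 pair all 15 were lower in both lines, with a median of -0.76 (adjusted p = 5.58e-10, and adjusted p = 0.754 with an estimated correlation).

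Genes of DNA replication and of mitosis were lower by small amounts. For replication, 16 of 19 had a lower mean, with a median of -0.30 (adjusted p = 0.0140, and adjusted p = 0.933 with an estimated correlation), led by RRM2, a ribonucleotide reductase subunit, at -0.36 ± 0.18 (SD, n = 3 lines), and the origin licensing factor CDC6 at -0.57 ± 0.63. For mitosis, 17 of 21 were lower, with a median of -0.19 (adjusted p = 0.0324, and adjusted p = 0.933 with an estimated correlation), led by MKI67, the Ki-67 proliferation marker, at -0.35 ± 0.27 and the spindle checkpoint kinase BUB1B at -0.36 ± 0.35. Both calls rested on SKM-1. Without its pair the medians were 0.036 (adjusted p = 0.827) and -0.011 (adjusted p = 0.811). Neither list, nor the MAP kinase list, had a gene called when adjusted over the list alone.

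The other lists were not called, with 0 genes adjusted over the list alone in each apart from the immediate early genes. Median log2 changes were 0.38 for monocyte and macrophage genes (adjusted p = 0.479), -0.21 for granulocyte genes (0.591), 0.16 for interferon response genes (0.144), 0.29 for NF-kB targets (0.392) and 0.052 for stem and progenitor genes (0.502), whose mean, at -0.48, had the opposite sign. They were 0.070 for the HOXA cluster and its partners (0.769), -0.029 for the leukemia stem cell score genes (0.811), 0.025 for MYC targets (0.828), -0.17 for p53 targets (0.811), 0.14 for the BCL2 family (0.392), -0.12 for endoplasmic reticulum chaperones (0.392) and -0.030 for oxidative phosphorylation (0.632). Ribosomal protein genes were at -0.11 (0.266), mitochondrially encoded genes at 0.039 (0.591), replication histones at -0.22 (0.392), leukocyte adhesion genes at 0.069 (0.557), and drug transport and metabolism genes at -0.12 (0.502). WNT targets were at -0.44 (0.557), JAK-STAT targets at -0.12 (0.811), lysosomal genes at -0.062 (0.838), T and NK cell markers at -0.50 (0.499) and B cell markers at -0.45 (0.940). For the HOXA, stem cell score, MYC, lysosomal and B cell lists the mean and the median differed in sign. The stem and progenitor median depended on the lines used, at -0.051 without the MOLM-14 pair, -0.45 without NOMO-1 and -0.44 without SKM-1. So did the stem cell score median, at -0.20, 0.44 and -0.087 in turn. Erythroid, megakaryocyte, and epithelial or stromal markers had 3, 3 and 4 measured members, too few for the test, with medians of -0.70, -0.66 and 0.70. Leaving out the SKM-1 pair raised the number of called lists from 8 to 15. Among these, monocyte genes (-0.37, adjusted p = 0.0108) and NF-kB targets (-0.85, adjusted p = 1.42e-07) were lower, and interferon response genes (0.39, adjusted p = 6.05e-05) were higher, each with an adjusted p of 0.754 with an estimated correlation. The first 2 turned with the line left out. NF-kB targets were called higher without the MOLM-14 pair (0.60, adjusted p = 0.00879) and without the NOMO-1 pair (0.80, adjusted p = 0.00378), and monocyte genes without the MOLM-14 pair (0.94, adjusted p = 0.00879). With an estimated correlation these adjusted p values were 0.965, 0.873 and 0.965. Ribosomal protein genes turned as well, at -0.28 without NOMO-1 (adjusted p = 0.00202, and adjusted p = 0.873 with an estimated correlation) and 0.096 without SKM-1 (0.0374 and 0.857). Also called without the SKM-1 pair were JAK-STAT targets (-0.37, adjusted p = 0.00370), leukocyte adhesion genes (-0.21, 0.0108), the HOXA list (0.31, 0.00469), oxidative phosphorylation genes (0.15, 0.00127) and MYC targets (0.22, 9.34e-04), with an adjusted p of 0.754 with an estimated correlation for the first 4 and 0.818 for the last. Without that pair WNT targets were at -0.016 and T and NK cell markers at -0.11, so the medians of these lists over 3 lines rest largely on SKM-1. B cell markers were at 0.12 without the SKM-1 pair, -0.077 without the NOMO-1 pair and -0.67 without the MOLM-14 pair. Their median within SKM-1 was -0.14.

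**Figure D2:**
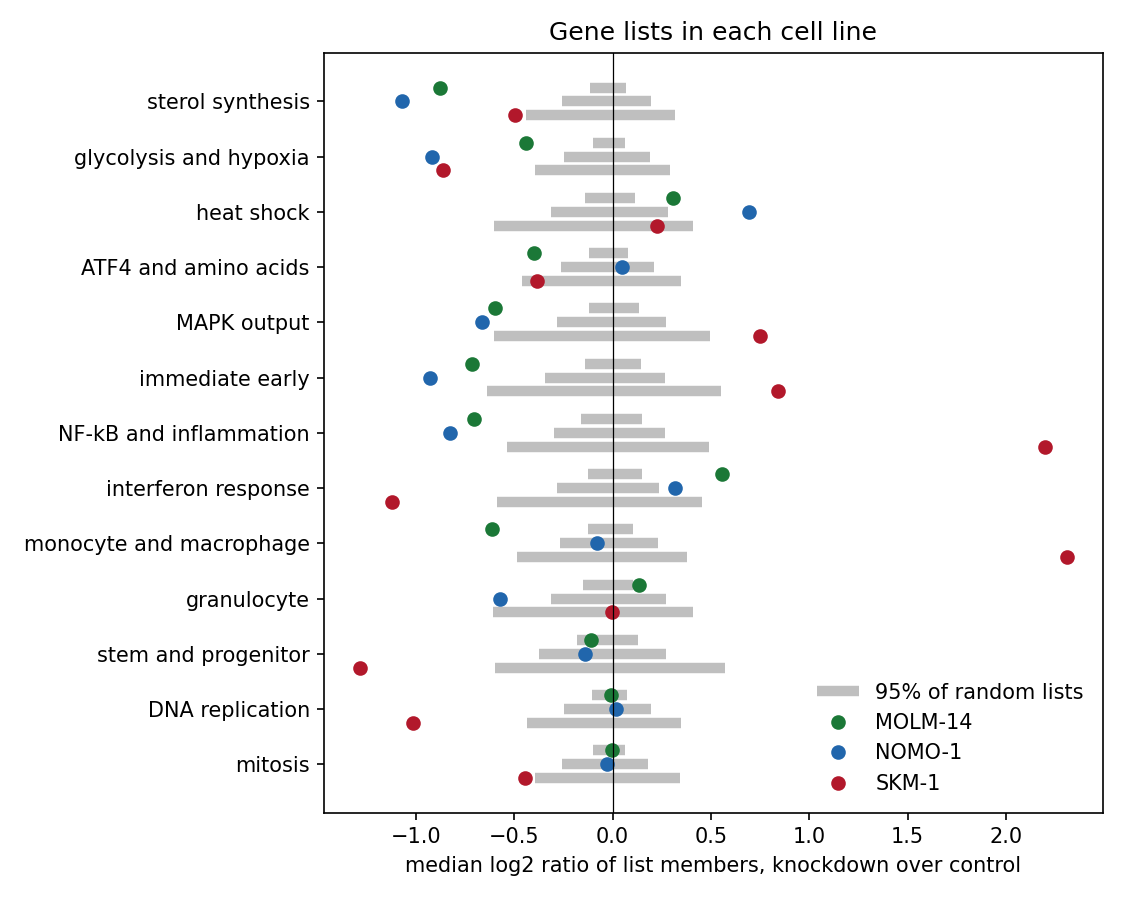
Median log2 ratio of knockdown over control (horizontal axis) of the members of 13 gene lists, 1 point per cell line, with grey bars for the central 95% of 10000 random lists of the same size and expression. Sterol synthesis (-0.88, -1.07 and -0.50) and glycolysis (-0.44, -0.92 and -0.86) lie left of 0 in MOLM-14, NOMO-1 and SKM-1, while MAPK output lies at -0.60, -0.67 and 0.75.

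How alike the 3 responses were was described across genes, which are not independent replicates. The same sign was found in all 3 lines for 30.6% of the 19575 genes (exact binomial 95% interval 29.9% to 31.2%), against 25% for independent signs. Of these genes 2863 were higher and 3121 lower. The log2 ratios had a Pearson r of 0.153 and a Spearman rho of 0.215 between MOLM-14 and NOMO-1. For NOMO-1 and SKM-1 they were 0.129 and 0.112, and for MOLM-14 and SKM-1 -0.037 and -0.0050. These depend on the filter. With none, the Pearson r was 0.082 for MOLM-14 and NOMO-1, 0.091 for NOMO-1 and SKM-1, and -0.021 for MOLM-14 and SKM-1. With a filter of 50 it was 0.190 for the first and -0.059 for the last.

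Within single lines the ratios are those of 2 libraries, with no replicate check and no test, and differences between lines were not tested. Members named from lists in this part were chosen after their values were seen. SKM-1 differed most between its libraries: 1884 genes were at least 2-fold higher and 2008 at least 2-fold lower, of 13510 with a normalized count of at least 100 in 1 of the 2 libraries. In NOMO-1 these numbers were 273 and 751 of 13278, and in MOLM-14 95 and 177 of 12614.

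In SKM-1, monocyte and macrophage genes were higher and genes of early granulocyte development were lower in the knockdown library. Of the 22 monocyte genes on the list 18 were tested, and CD14, CD163, MRC1 and CD68 were not among them. Of the 18, 14 were higher, 11 of them at least 2-fold, and 4 lower. The median log2 ratio was 2.31, at the 100th percentile of random lists of matched size and expression. It was 1.57 with no filter on low values and 1.87 with the authors' transformed values. S100A8 and S100A9, the subunits of calprotectin, went from normalized counts of 302 and 1254 to 73055 and 91617, and CD86, a costimulatory ligand, from 52.8 to 9816. All 19 NF-kB targets were higher, with a median of 2.20 (100th percentile). IL8 (now CXCL8), a neutrophil attractant, went from 528 to 28301. AQP9, a water and glycerol channel, went from 0 to 944 reads, at least 284-fold higher against a floor of 3 reads in the control library. STEAP4, a metalloreductase, was 468-fold higher (counting interval 200 to 1442) and F5, coagulation factor V, 304-fold (130 to 938). S100A12, another calcium-binding protein of myeloid cells, had 1 read in the control and 692 in the knockdown library, a ratio of 625 (112 to 24733).

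Most genes for proteins of primary granules, which promyelocytes make, stood at the other end in SKM-1. MPO (myeloperoxidase) went from a normalized count of 728824 to 6166 and ELANE (neutrophil elastase) from 81841 to 933. CTSG (cathepsin G) was 353-fold lower (counting interval 197 to 708). A list of 10 genes, named the primary granule list here, was written after the data were seen. It also holds MS4A3, which encodes a membrane protein, and RNASE2 and RNASE3, known best from eosinophil granules. Its median log2 ratio was -5.39 in SKM-1 (9 lower, with BPI higher at 1.28), -0.98 in NOMO-1 and 0.54 in MOLM-14. The granulocyte list, which also holds later markers, had a median of -0.0024 in SKM-1, with 4 members at least 2-fold higher, among them MMP9, and 5 at least 2-fold lower. CST7 (cystatin F) had 2225 reads in the control and 2 in the knockdown library, a ratio of 1231 (340 to 10172), and WNT7B had 322 and 0 reads, at least 119-fold lower. VIT was 319-fold lower (137 to 985). Of transcription factors active in progenitors, MYB went from 23234 to 1698 and GFI1 from 10526 to 1350. The stem and progenitor list had a median of -1.29 (percentile 0) with members going both ways: 6 of 10 were at least 2-fold lower, while MECOM, at 3.97, and MSI2, at 1.11, were at least 2-fold higher. DNA replication genes had a median of -1.01, with 10 of 19 at least 2-fold lower, and interferon response genes -1.12 (-0.58 with a pseudocount of 8), with 12 of 23 at least 2-fold lower.

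**Figure D3:**
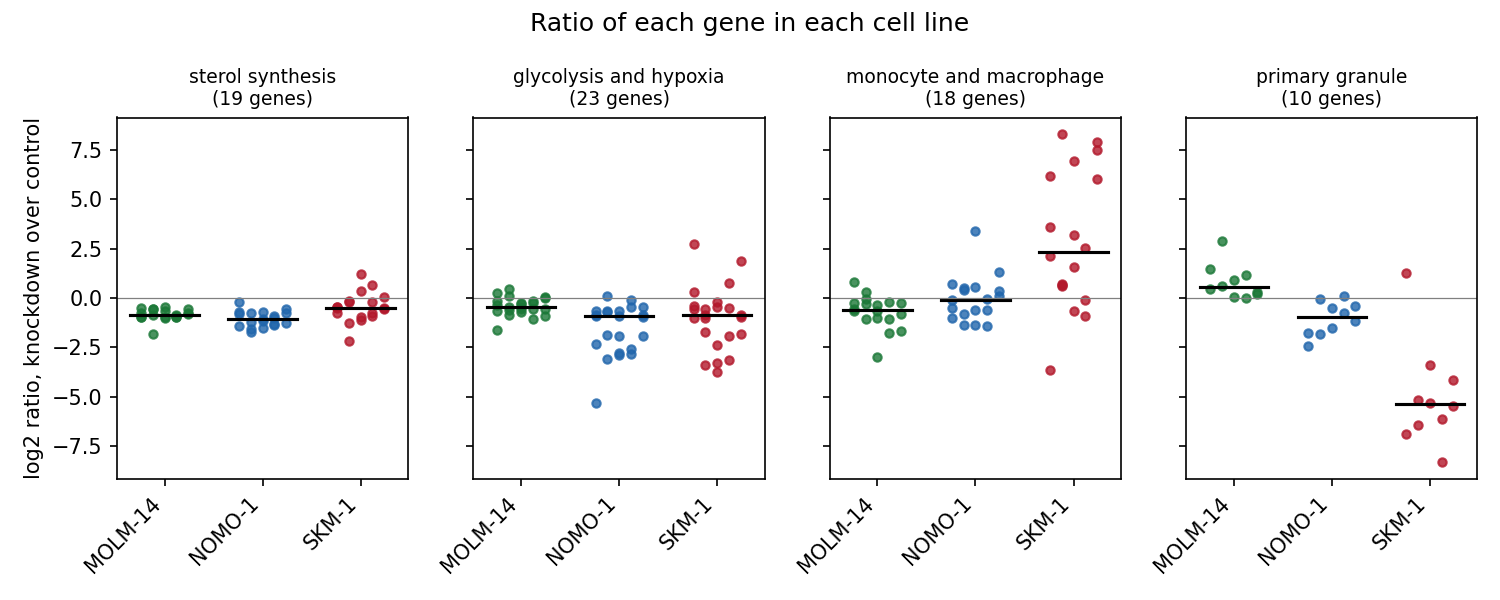
Log2 ratio of knockdown over control (vertical axis) of each member of 4 gene lists in each cell line, 1 point per gene, with a bar at the median. The primary granule list was written after the data were seen. Monocyte genes have a median of 2.31 in SKM-1 and -0.61 in MOLM-14, and primary granule genes -5.39 and 0.54, while sterol synthesis genes lie below 0 in each line by their median.

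In MOLM-14 the interferon response was the highest of the lists fixed in advance, with 21 of 23 members higher and a median log2 ratio of 0.56 (100th percentile). OAS3, an antiviral synthetase, went from a normalized count of 183 to 821. NF-kB targets, immediate early genes and monocyte genes had medians of -0.71, -0.72 and -0.61, each at percentile 0 of the random lists; with a pseudocount of 8 the NF-kB and monocyte medians were -0.39 and -0.29. PEG10, an imprinted gene of retroviral origin, was 26.8-fold higher (counting interval 13.9 to 59.4), the homeobox gene HMX2 25.4-fold (11.4 to 70.3), ZFP3 18.2-fold (7.52 to 57.2) and IGHM, the immunoglobulin mu chain, 8.78-fold (5.23 to 15.8). BHLHE22 was 10.3-fold lower (9.55 to 11.2), IL7R, the interleukin 7 receptor, 8.77-fold (6.96 to 11.2), GJC1 8.83-fold (5.87 to 13.8) and FLT1, a VEGF receptor, 8.17-fold (7.18 to 9.32).

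In NOMO-1 sterol synthesis and NF-kB targets had medians of -1.07 and -0.83 (percentile 0 for both), with 11 of 19 sterol genes at least 2-fold lower, and heat shock genes were at 0.69 (100th percentile). ADAMDEC1 was 49.1-fold higher (counting interval 22.3 to 135), the GTPase GIMAP4 18.8-fold (9.33 to 44.4), SRPX 18.8-fold (8.40 to 52.4) and MS4A1, which encodes CD20, 13.8-fold (11.7 to 16.4). SEMA5B, a semaphorin, was 41.1-fold lower (18.6 to 113), the kinase gene PNCK 31.2-fold (21.4 to 47.3) and ARG1 (arginase 1) 23.4-fold (14.4 to 40.6). POU2AF1, a B cell coactivator, had 111 reads in the control and 3 in the knockdown library, a ratio of 38.3 (12.8 to 189).

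The design also allowed each line to be set against the mean of the other 2, with shRNA as a term, as a secondary comparison. MOLM-14 was set apart by HMX3, a homeobox gene, and by interferon response genes. HMX3 had normalized counts of 882 and 1093 in its control and knockdown libraries and 0 in the other 4 libraries. PAX5, the B cell transcription factor, had 1194 and 1032 and at most 3.78 elsewhere, and LAMP5, a lysosome-associated membrane protein, 3794 and 4636 and at most 7.30 elsewhere. CTGF (now CCN2), TSKS and LINC01021 were the other 3 named as higher. NHLRC3 and PROSER1 were lower than in the other lines by log2 differences of -10.32 ± 0.26 and -10.12 ± 0.30 (SE), and GALNT14 had 0 counts in both MOLM-14 libraries. By limma, 6 of 11 genes of the HOXA list were higher in MOLM-14 at an adjusted p under 0.05 and at least 2-fold (8 adjusted over the list alone), including PBX3, a HOX cofactor, by 1.85 ± 0.20 and MEIS1 by 3.50 ± 0.74. Part of this came from low values in SKM-1: MEIS1 had normalized counts of 3047 and 3218 in MOLM-14, 2176 and 1715 in NOMO-1, and 121 and 11.9 in SKM-1. Of the interferon genes 10 of 23 were higher (12 adjusted over the list alone), led by IFIT2 at 4.57 ± 0.32, and MX1 was lower, by -2.21 ± 0.34. Of this list 6 genes were called lower in NOMO-1 and 5 in SKM-1. Those calls partly restate the MOLM-14 difference, because each line is set against the mean of the others. In all, 2987 genes were called for this line, 1296 higher and 1691 lower.

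NOMO-1 carried transcripts of CD3 chains, the signalling partners of the T cell receptor. CD3D had normalized counts of 3789 and 2961 in NOMO-1 and at most 20.9 elsewhere. With CD3G, CD3E and PRF1 (perforin) it made up the 4 of 6 T and NK cell markers called higher, also 4 when adjusted over the list alone. CD247, a further chain of that complex, went the other way without being called, at -2.57 ± 0.995 (SE, adjusted p = 0.165). MAGEA1, a cancer-testis antigen, had 4030 and 3673, the nuclear receptor RORB 5232 and 5653, and CEACAM6, a granulocyte adhesion protein, 7926 and 2178, while no other library exceeded 3.35 for these 3 genes. GDA, RAB3C and CD177 were the other higher ones. FOCAD and CAAP1 were lower by -10.48 ± 0.35 and -10.37 ± 0.35 (SE, log2), with at most 0.945 normalized counts in NOMO-1. ELANE was lower by -10.20 ± 1.55 (adjusted p = 0.0206). There were 1567 genes higher and 995 lower in NOMO-1, 2562 in all.

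SKM-1 differed by CDKN2A, which encodes the cell cycle inhibitor p16, with normalized counts of 5133 and 1843 against at most 2.23 elsewhere. SPARC, a matrix protein, had 12617 and 2906, and PLOD2, a collagen lysyl hydroxylase, 3622 and 2380. CHIC1, GSTM3 and MPDZ were also higher. MT1G had 0 counts in both SKM-1 libraries, with the caution that metallothionein copies share reads. VAT1L and BEX1 were lower by -10.60 ± 0.26 and -10.48 ± 0.20 (SE, log2). Genes of the ATF4 list were lower in SKM-1, 11 of 18 (12 adjusted over the list alone), with DDIT3, the stress factor CHOP, at -2.20 ± 0.22 and ASNS (asparagine synthetase) at -1.66 ± 0.24. HOXA list genes were lower for 5 of 11, also 5 adjusted over the list alone. Here 3051 genes were called, 1449 higher and 1602 lower. The 2 libraries of a line differ in their shRNA, so these contrasts use the scatter of the knockdown responses as their error.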

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

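In this part the checks of library identity and the comparison of interferon medians, with their bounds, were chosen after the results had been seen, as was the GC and length check of the primary granule genes, while that of the monocyte genes was not. For 11 gene lists the cell lines moved in opposite directions, each median lying outside the central 95% of random lists. With 1 library per line and condition none of these differences was tested.

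Monocyte and macrophage genes had a median log2 ratio of 2.31 in SKM-1 and -0.61 in MOLM-14. NF-kB targets stood at 2.20 in SKM-1 and -0.83 in NOMO-1, where TNF had ratios of 6.10 and -0.63. Immediate early genes were at 0.84 in SKM-1 and -0.93 in NOMO-1, and MAP kinase outputs at 0.75 and -0.67. Leukocyte adhesion genes were at 0.85 in SKM-1 and -0.40 in NOMO-1, and JAK-STAT targets at 1.01 and -0.69. MYC targets were at 0.35 in NOMO-1 and -0.49 in SKM-1, oxidative phosphorylation genes at 0.19 and -0.48, and ribosomal protein genes at 0.21 and -0.50. Granulocyte genes were at 0.13 in MOLM-14 and -0.57 in NOMO-1. Interferon response genes were at 0.56 in MOLM-14 and -1.12 in SKM-1. With a pseudocount of 8 the last was -0.58 and the monocyte median in MOLM-14 -0.29. The monocyte median in SKM-1 was 1.57 with no filter on low values.

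The first pattern weighed is the SKM-1 knockdown library, with monocyte genes high and primary granule genes low. Material of MOLM-14 or NOMO-1 is argued against, because 35 genes specific to those lines reached a median of 0.0766% of their own line's level. Near-total replacement by cells of another type is argued against too. A median of 34.8% of the control level remained for 44 genes specific to SKM-1, against 0.846% for MPO. Of these 44 genes 37 kept 10% or more, and the 90th percentile was 181%. They were specific only against MOLM-14 and NOMO-1, and MPO belongs to the pattern itself. These values cannot exclude a partial replacement. A GC or length trend does not account for it, since after correction the monocyte median was 2.21 and the primary granule median -5.29. What stays open, and was not tested, is an effect of the knockdown on the state of the cells. So do a partial replacement of the cells and effects of handling, of the hairpin on other targets, or of a separate preparation. The deposited column of this library carries an extra letter in its name. All of these are confounded in this library.

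The second is the interferon list, high in MOLM-14 and NOMO-1. Its medians there were 0.56 (21 of 23 members higher, 100th percentile of random lists) and 0.31 (16 of 23, 99.4th percentile). A response to shRNA common to the knockdown libraries would need SKM-1 to share it, and the lowest median of the 3 lines was -1.12, in SKM-1. That is a single library that moved broadly, and its median depends on the pseudocount (-0.58 with 8). In SKM-1 14 of 23 members were lower, 12 of them at least 2-fold. In all 3 lines 7 of 23 were higher, RSAD2, IFI44 and IFI44L among them. With 21, 16 and 9 members higher in MOLM-14, NOMO-1 and SKM-1, some overlap arises without a shared response. That count therefore decides nothing, and a common response stays open. The control libraries also received an shRNA, and an effect of NCAM1 itself was not tested.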

How the results depend on the processing

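Of 112 values for the 8 called lists under alternatives, 89 kept their direction and side of the threshold. Of the values within single lines 444 stayed and 15 moved, 2 of these being the gene counts below and the others list medians, mainly of monocyte genes and NF-kB targets, that kept their sign. NCAM1 kept its direction under all 15 alternatives. The count of genes called was 0 except for DESeq2, with 43. With an estimated correlation 0 lists were called, with unchanged medians: sterol -0.77, glycolysis -0.78, heat shock 0.51, ATF4 -0.40, NCAM1 partners -0.50, MAP kinase output -0.25, replication -0.30 and mitosis -0.19. With eBayes without trend 4 lists were called, and MAP kinase output (-0.25), replication (-0.30), mitosis (-0.19) and NCAM1 partners (-0.50) were lost. Without the block for the pairing by line, MAP kinase output (-0.25) and ATF4 (-0.40) were lost, genes at an unadjusted p under 0.05 went from 877 to 141, and 6 lists were called. Mitosis was lost under quantile normalization (-0.16) and NCAM1 partners with no filter (-0.50). Leaving out a line gave 7 to 15 called lists. Medians ranged from -0.60 to -0.0078 for MAP kinase output, from -0.43 to 0.036 for replication, which was reversed without SKM-1, from -0.25 to -0.011 for mitosis, from -0.46 to -0.21 for ATF4 and from -0.62 to -0.21 for NCAM1 partners. Sterol, glycolysis and heat shock were called with any 1 line left out, and none with an estimated correlation (adjusted p of 0.965, 0.873 and 0.754 for each list without MOLM-14, NOMO-1 and SKM-1). The share of genes with 1 sign in all lines was 23.4% with no filter, where many genes have 0 reads in both libraries of a line and so no sign, 32.3% with a filter of 50 and 31.7% with the authors' transformed values. NOMO-1 line genes numbered 1670 with the filter of 50, which tests fewer genes. With the transformed values 146 genes in MOLM-14 and 594 in NOMO-1 were at least 2-fold apart in either direction. The main setting gave 95 higher and 177 lower in MOLM-14, and 273 higher and 751 lower in NOMO-1. Other than the counts from fewer genes, the cause of these changes was not tested. Total-count scaling and quantile normalization left the median log2 ratio of all genes at 0.042 or less in size in each line. Depth limits the folds of genes near 0 reads, such as AQP9, S100A12, CST7 and WNT7B in SKM-1.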

Other observations

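All tests on the lists of this part (fatty acid, LXR, granule, metallothionein and MHC class II genes) used lists written after the data had been seen, while the GC and length checks and the splits of the libraries had been set before their results. Fatty acid synthesis genes were lower in MOLM-14 and NOMO-1, as the sterol genes were, with median log2 ratios of -0.64 and -0.71. In SKM-1 the median was -0.12, at percentile 47.03 of random lists, where the sterol list was at -0.50. The median change over the 3 lines was -0.54, and 8 of 12 were lower in all 3 lines, among them FADS2, a fatty acid desaturase, at -0.97 ± 0.36 (SD, n = 3 lines), ACLY, which makes cytosolic acetyl-CoA, at -0.65 ± 0.24, and FASN (fatty acid synthase) at -0.59 ± 0.27. ME1 (malic enzyme) went the other way, at 2.42 ± 2.21. By camera the list had an adjusted p of 8.64e-04 over the 6 lists, and an adjusted p of 0.647 with an estimated correlation.

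Other gene groups parted by line as well. Metallothioneins, metal-binding proteins whose copies share reads, had a median log2 ratio of 0.86 in MOLM-14, 1.53 in NOMO-1 and -1.32 in SKM-1, with MT2A at 0.80, 1.402 and -1.22. MHC class II genes, whose alleles map unevenly, were at 0.93, -0.14 and 1.11, and HLA-DRA at 1.05, -0.13 and 1.27. In SKM-1 8 of 10 were higher, while CIITA, at -1.29, and HLA-DQB1, at -0.13, were lower. Several rest on few reads there, with control counts of 0 for HLA-DQA1, 3.05 for HLA-DMB and 5.08 for HLA-DPB1. Primary granule genes were at 0.54, -0.98 and -5.39. Of 10 later granule genes only 5 were tested, with medians of -0.084, 0.46 and 0.048. Their SKM-1 median hides a wide spread, with MMP9 at 5.61, CHI3L1 at 4.14, CAMP at 0.048, ARG1 at -1.64 and PGLYRP1 at -1.93. CHI3L1, a secreted chitinase-like protein of that later list, went from a normalized count of 8339 to 146639 in SKM-1. Across the 3 lines camera gave adjusted p values of 0.199, 0.00125, 0.00177 and 0.766 for these 4 lists, and 0.707, 0.647, 0.647 and 0.791 with an estimated correlation.

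The third pattern weighed is the lower sterol and glycolysis lists. A GC or length trend is argued against, since after correction the medians were -0.75 (SE 0.17 over 3 lines) and -0.74 (SE 0.14). Lower activity of the SREBP factors, which drive both sterol and fatty acid genes, may account for the sterol part in MOLM-14 and NOMO-1, as a hypothesis that the fatty acid median of -0.54 (SE 0.19) could have gone against. In SKM-1 the fatty acid genes give it no support. Excess sterol in the cells would raise LXR targets, whose median was -0.34 (SE 0.15), within its error of the bound set beforehand, so this stays open. The use of an SE was settled after these values were seen: with no spread the LXR median would count against excess sterol, and with an SD the corrected sterol median would be undecided, while no test here bears on the biological side of the glycolysis genes.

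The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 0 genes, and the highest of the others 1846, in the splits that part only the SKM-1 pair. With the line as a block such a split measures the difference between the 2 SKM-1 libraries alone, so the structure it points to is the size of that difference. With 0 genes in the real split, 10 of 10 splits must call as many, so that count decides nothing. For gene lists the real split called 8, the lowest of all, and 10 of 10 splits called as many, with 14 the highest. The other 3 splits that part all 3 pairs called 0 genes each and 14, 9 and 9 lists.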
